A study of Acetivibrio thermocellus DSM 1313 with 12 samples.

How the data were processed

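RNA was measured in 12 libraries of Clostridium thermocellum, 3 from each of 4 groups: a control strain and a sulfite reductase mutant strain, each on cysteine or on sulfate. Per the labels' protocols, 50 ml cultures were sampled in mid-exponential growth at an optical density of about 0.6, RNA was depleted of rRNA, and 50-base single reads were sequenced. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Counts of replicates differed far more than counting noise allows (chi-square per degree of freedom 39.0 to 218). This argues against 1 library sequenced repeatedly, but not against repeated preparations from 1 culture. Libraries are named by group and replicate number.

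The authors deposited a table of read counts per gene, with no normalization per the file headers. They also deposited log2 fold changes per gene for 5 pairs of groups, and an adjusted p-value beside each, per the file headers. The submitters' processing notes name DRAGEN, DESeq and DESeq2 without saying which step each did. The aligner, the counting rule, the strand setting and the genome build are not given in the sources used here. Whether reads from overlapping or antisense genes were separated is therefore unknown. No coordinates are printed.

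Product names broken over lines in the count table were rejoined, which moved the counts of 154 genes from a continuation line. Of 3017 entries, 3 pairs sharing a symbol (fusA, gatA and porA) had identical counts. 1 entry of each pair was kept, as which locus the counts belong to is uncertain, leaving 3014. Of these, 2818 carry an older locus tag, 2682 matched the deposited lookup between strains and 1032 have a symbol, from the count table or else from the lookup. 16 had no count in any library. Members of gene families with near-identical copies are uncertain where reads could be shared. Total counts were 14693426 to 22305246 per library.

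Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were fitted in 1 quasi-likelihood model of all 12 libraries with a mean per group and TMM factors, so that the groups share 1 estimate of spread. Each contrast was tested with the quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A standard error is the absolute log2 fold change divided by the square root of F. Principal components used log2 CPM (each gene's count scaled by its library's total and TMM factor) with a prior count of 2. The replicate numbers were not used as a block.

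The groups, tests, alternatives, gene lists and the rule for naming genes were chosen before the data were examined. The rule names the deleted genes with the 5 genes on each side, the sulfate list, the 10 genes with the largest rise and the 10 with the largest fall in each comparison (5 and 5 for the interaction), and up to 4 members of each list with the smallest p. The largest changes needed a mean of at least 10 CPM and, except for the interaction, no overlap between the 3 libraries of one group and the 3 of the other. Other genes named were chosen after their values were seen.

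Of 21 gene lists matched on product names, the list of rRNA and tRNA was set aside, because it matched only enzymes. The other 20 were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and with an estimated one, and with fry, adjusted over lists and contrasts together. Camera asks whether a list's genes changed more than other genes, and fry whether they changed at all. Where most genes change, a list can thus pass with fry without standing out. They are sulfate uptake and reduction, siroheme and cobalamin synthesis, cysteine and methionine metabolism, iron-sulfur cluster and sulfur carrier, hydrogenases and ferredoxin redox enzymes, pyruvate fermentation, glycolysis and cellobiose use, cellulosome and glycoside hydrolases, ribosomal proteins, ATP synthase, flagella and chemotaxis, sporulation, chaperones and proteases, oxidative and thiol stress, branched-chain amino acid synthesis, arginine, histidine and tryptophan synthesis, nitrogen assimilation, purine and pyrimidine synthesis, iron and metal transport, and CRISPR and mobile elements. Matching on names brought in some members that do not do what a list's name says, such as flhG, a flagellar gene, in the siroheme list and a sorbitol dehydrogenase among chaperones. Counts of list genes given with RLE factors or library totals alone are adjusted over all genes.

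The model was tested on simulated counts drawn from the mean levels of the control strain on cysteine, each gene's estimated dispersion and the library totals, with 200 of 2955 genes changed and a list of 20 more raised 1.5-fold. The seeded list gave a camera p of 1.26e-11 in the control strain comparison (1.09e-04 with an estimated correlation), and 3.74e-09 for the interaction (1.99e-04), and 0 of 20 unchanged lists were called. Genes were drawn independently, so this does not test lists whose genes vary together, and in the real data the estimated correlation within lists reached 0.761. For sulfate against cysteine in the control strain edgeR recovered 71.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold, and 3.55% of its calls were false. For the interaction it recovered 34.3%, 80.6% and 97.0%, and 3.92% of its calls were false. DESeq2 had 5.34% false calls in the control strain comparison and 8.43% for the interaction. In the simulation only 1 group differed and most genes did not change. In the real data 27.9% to 74.3% of genes were called, so these rates need not hold there. Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals alone, no filter, a mean count of at least 50, only the 6 libraries compared, the 10 most abundant genes left out, the replicate number as a block, stricter thresholds, a prior count of 2 and each library left out in turn. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.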

Results

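RNA was sequenced in 12 libraries of Clostridium thermocellum, a cellulose-degrading anaerobe, in 4 groups of 3. The control strain lacks hpt, a hypoxanthine phosphoribosyltransferase gene. The mutant strain lacks hpt and a sulfite reductase gene, whose product reduces sulfite to sulfide. Each strain was grown on cellobiose with either 5.7 mM cysteine or 28.2 mM sodium sulfate as its sole source of sulfur. Total counts ran from 14693426 to 22305246 per library, and the 10 most abundant genes held 17.1% to 23.5% of them. Of 3014 genes, 2955 passed the expression filter and were tested.

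The deleted genes were examined first. Clo1313_0124, annotated as a nitrite and sulphite reductase, had 1072, 1170 and 1248 counts in the control strain on cysteine and 4561, 6290 and 3976 on sulfate. In the mutant strain it had 12, 5 and 10 counts on cysteine and 7, 3 and 8 on sulfate. Its log2 fold change between strains was -7.21 ± 0.25 on cysteine (SE, n = 3 per group, adjusted p = 2.46e-11) and -9.21 ± 0.26 on sulfate (adjusted p = 1.42e-12). The hpt gene, Clo1313_2927, had 8 to 34 counts in every library, in both strains, near the floor of the data. Each of the 6 mutant libraries thus had at most 12 counts of Clo1313_0124, and each of the 6 control strain libraries at least 1072.

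**Figure D1:**
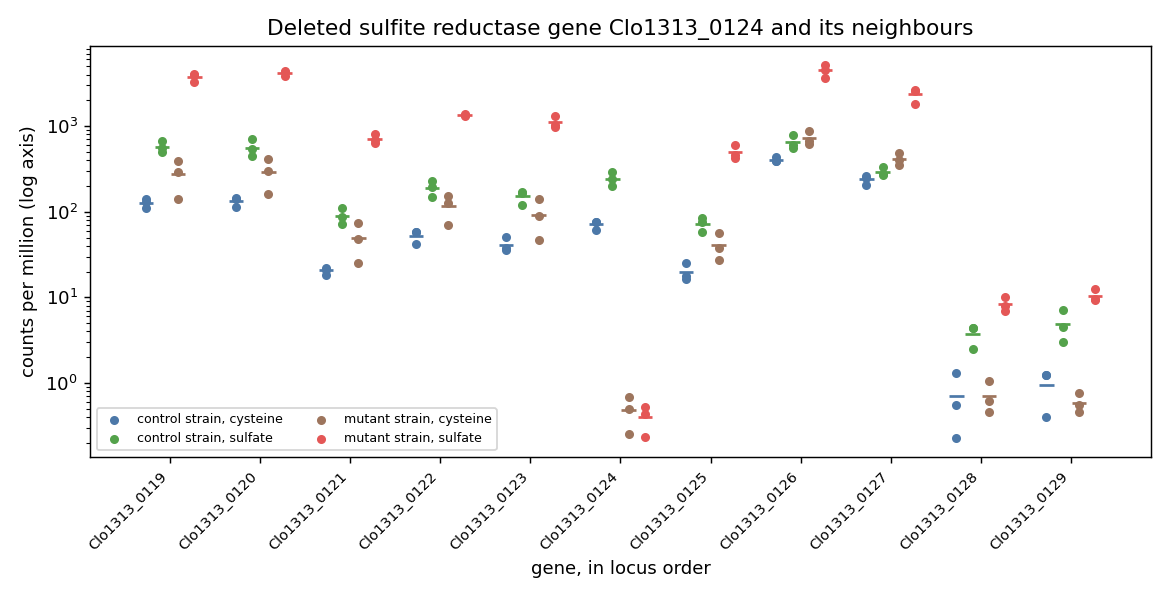
CPM (counts scaled by the library's total and TMM factor) on a log axis for Clo1313_0124 and the 5 genes on each side, in locus order. Points are libraries, 3 per group, short lines are group means, and Clo1313_0124 is near the floor in the 6 mutant libraries. The 5 genes on each side are highest in the mutant strain on sulfate, with Clo1313_0128 and Clo1313_0129 at low levels in all groups.

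The mutant strain on sulfate lay apart from the other groups. The first principal component of log2 CPM held 75% of the variance and placed these 3 libraries at 49.8 to 52.6, against -24.3 to -4.43 for the other libraries, and the second held 13%.

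**Figure D2:**
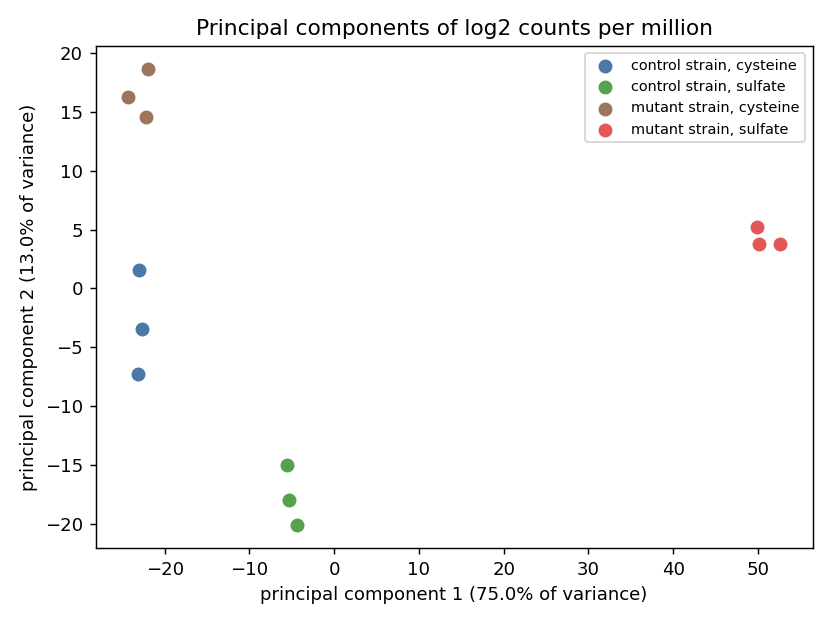
Libraries on the first and second principal components of log2 CPM, which hold 75% and 13% of the variance. Points are libraries coloured by group, and the 3 libraries of the mutant strain on sulfate stand alone at the right.

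The first comparison asks how the control strain changes when sulfate replaces cysteine. Genes of sulfate uptake and reduction rose, among them cysP, a sulfate transporter subunit, with a log2 fold change of 2.71 ± 0.25 (SE, n = 3 per group, adjusted p = 1.40e-06). The transporter gene cysU rose by 2.57 ± 0.26, cysW by 2.13 ± 0.22 and cysA by 2.07 ± 0.24. The reduction genes cysD, cysH, cysNC and Clo1313_0124 rose by 2.19 ± 0.26, 1.87 ± 0.25, 2.07 ± 0.26 and 1.77 ± 0.16. Genes upstream of siroheme, the cofactor of sulfite reductase, rose too: hemC by 3.08 ± 0.22, cobA-hemD by 3.03 ± 0.22 and hemB by 3.04 ± 0.22. The 10 largest rises lay in a run of 12 adjacent genes, Clo1313_0372 to Clo1313_0383, which rose by a median of 5.11. Their annotations include a cobalamin-binding protein, methyltransferases, an ABC transporter and a ferredoxin, and the run was picked after its values were seen.

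In the sulfate uptake and reduction list 8 of 8 tested genes rose and 0 fell (8 and 0 adjusted over the list alone), and the median was 2.10 (camera adjusted p = 7.54e-15, and adjusted p = 0.127 with an estimated correlation). In the siroheme and cobalamin synthesis list 10 of 14 tested genes rose and 0 fell (10 and 0 adjusted over the list alone), and the median was 1.58 (camera adjusted p = 4.61e-18, and adjusted p = 0.0946 with an estimated correlation). The 10 largest falls lay between Clo1313_2319 and Clo1313_2338. They included metY, which makes homocysteine from O-acetylhomoserine, at -2.02 ± 0.20, and the ABC transporter genes Clo1313_2336 and Clo1313_2338 at -1.87 ± 0.16 and -1.67 ± 0.12. The nearby ogt, a DNA repair methyltransferase gene, changed by -1.74 ± 0.17. The genes nifD, nifK and nifH, annotated as nitrogenase or hydrogenase components, changed by -1.37 ± 0.15, -1.39 ± 0.15 and -1.36 ± 0.14.

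Among ribosomal proteins 0 of 56 tested genes rose and 18 fell (0 and 20 adjusted over the list alone, with camera adjusted p = 1.45e-05, and adjusted p = 0.585 with an estimated correlation). Examples are rplK at -0.68 ± 0.13 and rpmI at -0.98 ± 0.20. Among genes of glycolysis and cellobiose use 3 of 25 tested genes rose and 9 fell (4 and 9 adjusted over the list alone, 8 and 6 with library totals alone), including gapA at -0.97 ± 0.17, pgk at -0.91 ± 0.11 and eno at -0.90 ± 0.14 (camera adjusted p = 0.0474, and adjusted p = 0.557 with an estimated correlation). The call for glycolysis and cellobiose use ended without control cysteine replicate 1, control sulfate replicate 3, mutant cysteine replicates 2 or 3 or mutant sulfate replicate 2 (camera adjusted p = 0.0513 to 0.0962) and with the replicate number as a block (adjusted p = 0.0599). The median of the list was -0.20, and 0.00 with library totals alone. Among genes of arginine, histidine and tryptophan synthesis 1 of 28 tested genes rose and 14 fell (1 and 14 adjusted over the list alone, 6 and 7 with library totals alone), led by argB at -1.05 ± 0.12 (camera adjusted p = 0.00559, and adjusted p = 0.585 with an estimated correlation). The median was -0.33, and -0.14 with library totals alone. For flagella and chemotaxis 4 of 85 tested genes rose and 19 fell (4 and 19 adjusted over the list alone, 11 and 11 with library totals alone, with camera adjusted p = 0.00401, and adjusted p = 0.585 with an estimated correlation). 1 example is flagellin fliC at -1.07 ± 0.20. The median of that list was -0.18, and it was 0.01 when libraries were scaled by their totals alone. Acetate genes pta and ackA changed by -0.83 ± 0.13 and -0.82 ± 0.14, and the ferrous iron transporter genes feoA and feoB by -0.99 ± 0.17 and -1.05 ± 0.18. No other list was called in this comparison. CRISPR and mobile elements passed with library totals alone (adjusted p = 0.0457). Cysteine and methionine metabolism passed with fry (adjusted p = 0.0325). The iron-sulfur list passed with fry (adjusted p = 0.00763). The cellulosome list passed with fry (adjusted p = 0.0230). The median, mean and test differed in sign for 4 lists, none of them called: pyruvate fermentation, oxidative and thiol stress, nitrogen assimilation, and iron and metal transport.

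By edgeR's quasi-likelihood test, 825 genes were called, 422 higher and 403 lower, and 99 of them changed at least 2-fold. With library totals alone 1106 were called, 915 higher and 191 lower, as the median of all genes moved from 0.02 to 0.21. The count was 530 without control strain, cysteine replicate 2 and 501 without control strain, cysteine replicate 3.

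The second comparison asks the same of the mutant strain, which lacks Clo1313_0124. The run of 12 genes from Clo1313_0372 was again highest, with the cobalamin-binding protein gene Clo1313_0372 at 8.70 ± 0.25 (SE, n = 3 per group, adjusted p = 3.37e-13). Genes of tetrapyrrole synthesis rose, with hemA at 6.20 ± 0.23 and hemC at 6.29 ± 0.24. Sulfate transporter genes cysP and cysU rose by 4.31 ± 0.27 and 4.30 ± 0.28, and cysH, the reductase of activated sulfate, by 4.02 ± 0.27. Other rises were cooS, a carbon monoxide dehydrogenase gene, at 5.08 ± 0.18, ssuA, a transporter substrate-binding protein gene, at 4.86 ± 0.18, and spoVR, a sporulation gene, at 4.62 ± 0.12.

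In the sulfate list 7 of 8 tested genes rose and 0 fell (7 and 0 adjusted over the list alone), where the deleted gene did not pass (camera adjusted p = 2.14e-04, and adjusted p = 0.473 with an estimated correlation). In the siroheme and cobalamin list 10 of 14 tested genes rose and 3 fell (10 and 3 adjusted over the list alone, with camera adjusted p = 1.73e-06, and adjusted p = 0.145 with an estimated correlation). The 3 that fell do not make siroheme or cobalamin: Clo1313_0007 (parA, chromosome partition) at -0.57 ± 0.09, Clo1313_1733 (flhG, flagellar placement) at -2.79 ± 0.14 and Clo1313_2759 (an rRNA methyltransferase) at -1.24 ± 0.11. For cysteine and methionine metabolism 13 of 15 tested genes rose and 1 fell (13 and 1 adjusted over the list alone, with camera adjusted p = 9.41e-05, and adjusted p = 0.134 with an estimated correlation). Examples are cysteine synthase gene cysK (Clo1313_2532) at 4.11 ± 0.19, metC at 3.23 ± 0.18 and cysE at 2.61 ± 0.14. For iron-sulfur cluster and sulfur carrier genes 17 of 20 tested genes rose and 1 fell (17 and 1 adjusted over the list alone, with camera adjusted p = 0.00131, and adjusted p = 0.127 with an estimated correlation). 1 example is cysteine desulfurase Clo1313_1570 at 2.71 ± 0.10. For nitrogen assimilation 26 of 28 tested genes rose and 2 fell (26 and 2 adjusted over the list alone, with camera adjusted p = 5.97e-05, and adjusted p = 0.367 with an estimated correlation). Examples are glutamate synthase Clo1313_2035 at 3.95 ± 0.18 and glutamine synthetase glnA (Clo1313_2303) at 3.34 ± 0.22. This list also holds Clo1313_2333, annotated as a diguanylate cyclase, at 2.13 ± 0.14.

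For chaperones and proteases 17 of 23 tested genes rose and 2 fell (17 and 2 adjusted over the list alone, with camera adjusted p = 0.00176, and adjusted p = 0.145 with an estimated correlation). Examples are clpC, a protease subunit gene, at 3.09 ± 0.14 and lon at 1.89 ± 0.12. For oxidative and thiol stress 12 of 17 tested genes rose and 1 fell (12 and 1 adjusted over the list alone, 11 and 3 with library totals alone, with camera adjusted p = 4.67e-04, and adjusted p = 0.145 with an estimated correlation). Examples are the thioredoxin reductase genes trxB at 2.77 ± 0.12 for Clo1313_2618 and 2.53 ± 0.11 for Clo1313_2617. Members outside these names included the sorbitol dehydrogenase Clo1313_0076 among chaperones, which fell, and cysH, counted among oxidative and thiol stress genes as well as in the sulfate list. For branched-chain amino acid synthesis 10 of 12 tested genes rose and 1 fell (10 and 1 adjusted over the list alone, with camera adjusted p = 0.0474, and adjusted p = 0.585 with an estimated correlation). 1 example is ilvD at 1.57 ± 0.12. The call for branched-chain synthesis ended without control cysteine replicates 1 or 3, control sulfate replicate 3, mutant cysteine replicate 2 or mutant sulfate replicate 2 (camera adjusted p = 0.0510 to 0.0662) and with the replicate number as a block (adjusted p = 0.0599). For hydrogenases and ferredoxin redox enzymes 27 of 44 tested genes rose and 12 fell (27 and 12 adjusted over the list alone, with camera adjusted p = 0.00866, and adjusted p = 0.484 with an estimated correlation). 1 example is ferredoxin Clo1313_0066 at 2.10 ± 0.11. For the cellulosome and glycoside hydrolases 55 of 94 tested genes rose and 26 fell (55 and 27 adjusted over the list alone, with camera adjusted p = 0.0291, and adjusted p = 0.585 with an estimated correlation). 1 example is Clo1313_0350 at 2.52 ± 0.10. The call for cellulosome genes ended without mutant sulfate replicate 1 (camera adjusted p = 0.0689).

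Flagella and chemotaxis genes fell as a group, where 4 of 85 tested genes rose and 75 fell (4 and 75 adjusted over the list alone), and the median was -1.88 (camera adjusted p = 2.28e-29, and adjusted p = 0.0946 with an estimated correlation). Chemotaxis genes cheA, cheW and cheR changed by -4.30 ± 0.15, -4.03 ± 0.14 and -4.11 ± 0.15. The 10 largest falls were cheA, cheW and cheR with Clo1313_0137 to Clo1313_0143, annotated with radical SAM proteins and glycosyl transferases, where Clo1313_0142 changed by -4.63 ± 0.18. For ATP synthase 6 of 15 tested genes rose and 8 fell (6 and 8 adjusted over the list alone, 3 and 8 with RLE factors, 0 and 8 with library totals alone, with camera adjusted p = 0.00178, and adjusted p = 0.484 with an estimated correlation). Examples are the V-type subunit genes ntpA and ntpC at -3.11 ± 0.14 and -3.02 ± 0.11. For arginine, histidine and tryptophan synthesis 4 of 28 tested genes rose and 17 fell (4 and 17 adjusted over the list alone, with camera adjusted p = 0.0157, and adjusted p = 0.598 with an estimated correlation). 1 example is argB at -3.01 ± 0.14. For glycolysis and cellobiose use 6 of 25 tested genes rose and 17 fell (6 and 17 adjusted over the list alone, 1 and 18 with library totals alone, with camera adjusted p = 0.0238, and adjusted p = 0.485 with an estimated correlation). 1 example is pgk at -1.89 ± 0.12. Lists not called were pyruvate fermentation (camera adjusted p = 0.896, its median, mean and test differing in sign), ribosomal proteins (0.267), sporulation (0.0526), purine and pyrimidine synthesis (0.0910), iron and metal transport (0.431) and CRISPR and mobile elements (0.424). Sporulation passed without control cysteine replicate 2, control sulfate replicate 1, mutant cysteine replicate 1 or mutant sulfate replicates 1 or 2 (camera adjusted p = 0.0330 to 0.0454), with fry (adjusted p = 7.51e-06), with library totals alone (adjusted p = 0.0322) and with no filter on low counts (adjusted p = 0.0495). Purine and pyrimidine synthesis passed without mutant cysteine replicate 1 (camera adjusted p = 0.0330) and with fry (adjusted p = 0.00231). Iron and metal transport passed with fry (adjusted p = 1.90e-06). CRISPR and mobile elements passed with fry (adjusted p = 7.28e-04).

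By the same test, 2196 genes were called, 1199 higher and 997 lower, and 1110 changed at least 2-fold. With library totals alone 2165 were called, 829 higher and 1336 lower, as the median of all genes moved from 0.12 to -0.23.

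**Figure D3:**
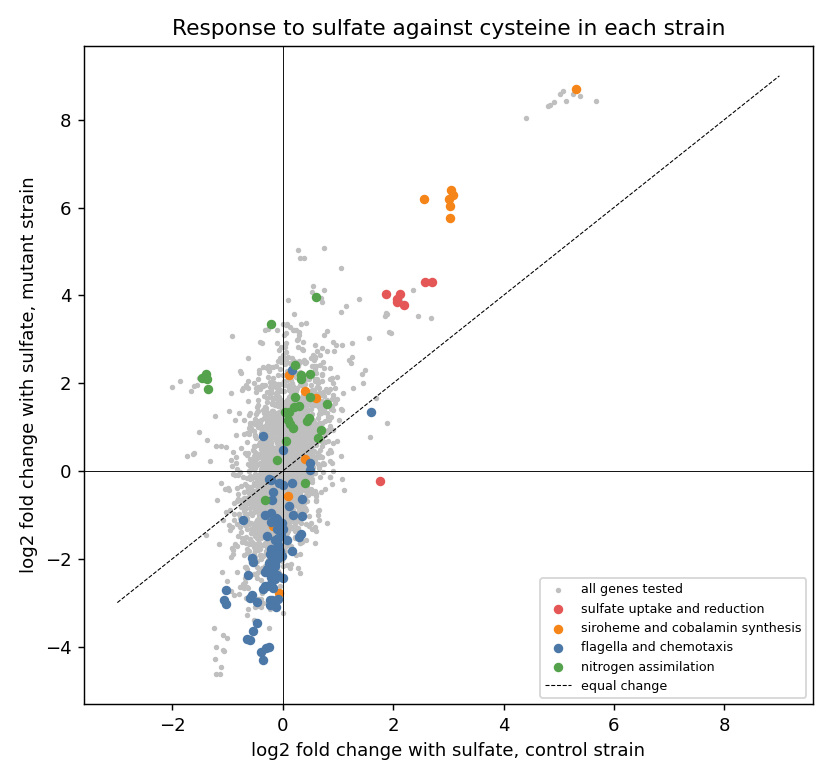
Log2 fold change of sulfate against cysteine in the control strain (horizontal) and the mutant strain (vertical), 1 point per tested gene, with 4 lists coloured and a dashed line of equal change. Siroheme genes reach 6.29 in the mutant strain against 3.08 in the control strain for hemC, and 75 of 85 flagella and chemotaxis genes fell in the mutant strain, with a median of -1.88.

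The third comparison sets the strains side by side on cysteine. Motility genes were higher in the mutant strain: of the flagella and chemotaxis list 72 of 85 tested genes were higher and 0 lower (76 and 0 adjusted over the list alone), and the median was 0.76 (camera adjusted p = 5.80e-30, and adjusted p = 0.0946 with an estimated correlation). Examples are flaG at 1.24 ± 0.13 and flgG at 1.10 ± 0.12 (SE, n = 3 per group). The intact genes of the sulfate list were higher as well, with cysP at 1.54 ± 0.24 and cysU at 1.55 ± 0.25. Some of them lie close to the deleted Clo1313_0124, among them cysH (Clo1313_0118), cysD (Clo1313_0119) and cysNC (Clo1313_0120). For these a local effect of the deletion cannot be told apart. The median of the intact sulfate list genes was 159 CPM in mutant cysteine replicate 1 and 297 and 414 in replicates 2 and 3. It was 110 to 142 CPM in the control strain libraries. Clo1313_0372 was higher by 1.82 ± 0.21, at a low level: the median of Clo1313_0372 to Clo1313_0383 was 3.88 to 4.35 CPM in the control strain libraries and 7.01 to 11.8 in the mutant strain libraries. The largest rises were Clo1313_0543, a sigma factor gene, at 2.35 ± 0.14 and its neighbour Clo1313_0544 at 2.29 ± 0.13.

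In the sulfate list 7 of 8 tested genes were higher and 1 lower (7 and 1 adjusted over the list alone), and the mean was 0.28 against a median of 1.32 because the deleted gene is a member (camera adjusted p = 0.327, and adjusted p = 0.823 with an estimated correlation). For the cellulosome and glycoside hydrolases 9 of 94 tested genes were higher, 30 were lower and most were not called (11 and 33 adjusted over the list alone, with camera adjusted p = 0.00169, and adjusted p = 0.484 with an estimated correlation). Examples are pectate lyase Clo1313_2843 at -1.55 ± 0.17 and cellobiosidase Clo1313_1021 at -1.43 ± 0.14. For ATP synthase 7 of 15 tested genes were higher, 0 were lower and the rest were not called (7 and 0 adjusted over the list alone, with camera adjusted p = 0.00888, and adjusted p = 0.555 with an estimated correlation). 1 example is ntpA at 0.92 ± 0.13. Besides the deleted gene, the largest falls were a Spo0E family gene, CLO1313_RS09390, at -2.79 ± 0.30, the response regulator Clo1313_0401 at -2.30 ± 0.22 and the sensor kinase Clo1313_0402 at -1.95 ± 0.16. No other list was called. The median, mean and test differed in sign for 5 of these: cysteine and methionine metabolism, hydrogenases and ferredoxin redox enzymes, sporulation, chaperones and proteases, and branched-chain amino acid synthesis. The sulfate list passed without mutant cysteine replicate 1 (camera adjusted p = 6.58e-05). The siroheme and cobalamin list passed without mutant cysteine replicate 1 (camera adjusted p = 0.0276). Arginine, histidine and tryptophan synthesis passed without control cysteine replicate 2, control sulfate replicates 1, 2 or 3, mutant cysteine replicate 3 or mutant sulfate replicate 1 (camera adjusted p = 0.00470 to 0.0498) and with library totals alone (adjusted p = 0.0464). Iron and metal transport passed with fry (adjusted p = 0.00238).

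The test called 907 genes, 477 higher and 430 lower, and 156 changed at least 2-fold. Directly beside the deletion, Clo1313_0123 was also higher by 1.16 ± 0.29 and Clo1313_0125 by 1.04 ± 0.24. For Clo1313_0123 the strains overlapped, with 46.2, 89.2 and 141 CPM in the mutant strain against 37.4, 35.4 and 50.9. Clo1313_0128 and Clo1313_0129 were near the floor on cysteine in both strains.

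The fourth comparison sets the strains side by side on sulfate. Sulfonate transporter gene ssuC was 5.07 ± 0.16 higher in the mutant strain (SE, n = 3 per group, adjusted p = 2.06e-12), ssuA 5.02 ± 0.18, cooS 4.91 ± 0.18 and Clo1313_0372 5.21 ± 0.21. The tetrapyrrole gene hemA was 4.14 ± 0.21 higher and cysH 3.37 ± 0.26. The chaperonin gene groEL was higher by 2.76 ± 0.17, and nifD by 3.48 ± 0.16. Besides the deleted gene, the largest falls included Clo1313_0401 at -3.02 ± 0.22, cheA at -2.99 ± 0.14, the chemoreceptor gene mcp (Clo1313_0707) at -2.92 ± 0.16 and Clo1313_1279, a regulator of fatty acid synthesis, at -2.88 ± 0.13.

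In the cysteine and methionine list 12 of 15 tested genes were higher and 1 lower (12 and 1 adjusted over the list alone, with camera adjusted p = 5.59e-07, and adjusted p = 0.0946 with an estimated correlation). 1 example is patB at 3.28 ± 0.18. For nitrogen assimilation 25 of 28 tested genes were higher and 2 lower (25 and 2 adjusted over the list alone, with camera adjusted p = 6.16e-07, and adjusted p = 0.200 with an estimated correlation). For oxidative and thiol stress 12 of 17 tested genes were higher and 2 lower (12 and 2 adjusted over the list alone, 11 and 4 with library totals alone, with camera adjusted p = 1.05e-04, and adjusted p = 0.138 with an estimated correlation). 1 example is msrA, which repairs oxidised methionine, at 2.18 ± 0.15. For chaperones and proteases 16 of 23 tested genes were higher and 2 lower (16 and 2 adjusted over the list alone, 12 and 4 with library totals alone, with camera adjusted p = 9.70e-04, and adjusted p = 0.138 with an estimated correlation). For siroheme and cobalamin synthesis 10 of 14 tested genes were higher and 4 lower (10 and 4 adjusted over the list alone, with camera adjusted p = 2.28e-04, and adjusted p = 0.334 with an estimated correlation). In the sulfate list 7 of 8 tested genes were higher and 1 lower (7 and 1 adjusted over the list alone, with camera adjusted p = 0.0291, and adjusted p = 0.585 with an estimated correlation). For iron-sulfur cluster and sulfur carrier genes 14 of 20 tested genes were higher and 5 lower (15 and 5 adjusted over the list alone, 10 and 6 with library totals alone, with camera adjusted p = 0.00310, and adjusted p = 0.145 with an estimated correlation). For branched-chain amino acid synthesis 10 of 12 tested genes were higher and 1 lower (10 and 1 adjusted over the list alone, with camera adjusted p = 0.00933, and adjusted p = 0.509 with an estimated correlation). 1 example is leuD at 1.29 ± 0.13. For hydrogenases and ferredoxin redox enzymes 25 of 44 tested genes were higher and 11 lower (25 and 11 adjusted over the list alone, 21 and 19 with library totals alone, with camera adjusted p = 0.00287, and adjusted p = 0.484 with an estimated correlation). The median of the hydrogenase list was 0.55, and 0.01 with library totals alone. For sporulation 39 of 83 tested genes were higher and 13 lower (39 and 13 adjusted over the list alone, 25 and 32 with library totals alone, with camera adjusted p = 0.0492, and adjusted p = 0.484 with an estimated correlation). The gene spoVR was 3.20 ± 0.12 higher, and the list's median of 0.38 was -0.16 with library totals alone. The call for the sulfate list ended without control sulfate replicate 3 (camera adjusted p = 0.0753). The call for sporulation ended without control cysteine replicates 1 or 3, control sulfate replicate 2, mutant cysteine replicates 2 or 3 or mutant sulfate replicate 3 (camera adjusted p = 0.0501 to 0.0814) and with the replicate number as a block (adjusted p = 0.0623).

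Flagella and chemotaxis genes were lower, where 10 of 85 tested genes were higher and 68 lower (10 and 68 adjusted over the list alone), and the median was -1.08 (camera adjusted p = 2.42e-13, and adjusted p = 0.186 with an estimated correlation). For arginine, histidine and tryptophan synthesis 3 of 28 tested genes were higher and 16 lower (3 and 16 adjusted over the list alone, with camera adjusted p = 0.00880, and adjusted p = 0.585 with an estimated correlation). 1 example is argB at -2.48 ± 0.13. For purine and pyrimidine synthesis 4 of 22 tested genes were higher and 15 lower (5 and 15 adjusted over the list alone, 2 and 18 with library totals alone, with camera adjusted p = 0.0376, and adjusted p = 0.633 with an estimated correlation). 1 example is pyrB at -1.40 ± 0.13. For ATP synthase 2 of 15 tested genes were higher and 8 lower (2 and 7 adjusted over the list alone, 0 and 11 with library totals alone, with camera adjusted p = 0.0295, and adjusted p = 0.585 with an estimated correlation). For glycolysis and cellobiose use 4 of 25 tested genes were higher and 14 lower (4 and 14 adjusted over the list alone, 2 and 21 with library totals alone, with camera adjusted p = 0.0440, and adjusted p = 0.555 with an estimated correlation). The other 5 lists were not called. Of these, pyruvate fermentation and ribosomal proteins had a median, mean and test that differed in sign. The medians of cellulosome, ribosomal, iron and CRISPR lists were above 0 here and below 0 with library totals alone. CRISPR and mobile elements passed with fry (adjusted p = 2.36e-04) and with library totals alone (adjusted p = 0.0487). The cellulosome list passed with fry (adjusted p = 0.00776). Iron and metal transport passed with fry (adjusted p = 3.38e-07). The call for glycolysis and cellobiose use ended without control cysteine replicate 1 or mutant sulfate replicates 2 or 3 (camera adjusted p = 0.0513 to 0.0617). The call for purine and pyrimidine synthesis ended without control sulfate replicate 2 (camera adjusted p = 0.0513). The call for ATP synthase ended without mutant sulfate replicate 1 (camera adjusted p = 0.0628).

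The test called 2037 genes, 1025 higher and 1012 lower, and 930 changed at least 2-fold. With library totals alone 2330 were called, 602 higher and 1728 lower, as the median of all genes moved from 0.02 to -0.52. Of the 1635 genes called both ways, 1614 kept their direction.

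The last comparison tests whether the change with sulfate differs between the strains. It was more positive in the mutant strain for ssuC by 4.75 ± 0.20 (SE, n = 3 per group, adjusted p = 3.63e-10), for ssuA by 4.55 ± 0.23, for cooS by 4.34 ± 0.22 and for metY by 3.93 ± 0.28. It was negative for cheA, at -3.95 ± 0.19, for mcp, at -3.76 ± 0.22, and for ntpA, at -2.72 ± 0.18. Of the flagella and chemotaxis list 3 of 85 tested genes had a positive interaction and 72 had a negative one (3 and 75 adjusted over the list alone, with camera adjusted p = 3.87e-31, and adjusted p = 0.0946 with an estimated correlation). Of the cysteine and methionine list 13 of 15 tested genes had a positive interaction and 1 had a negative one (13 and 1 adjusted over the list alone, with camera adjusted p = 2.64e-07, and adjusted p = 0.0946 with an estimated correlation). In nitrogen assimilation 21 of 28 tested genes had a positive interaction and 1 had a negative one (23 and 2 adjusted over the list alone, 12 and 3 with library totals alone, with camera adjusted p = 5.09e-06, and adjusted p = 0.251 with an estimated correlation). In oxidative and thiol stress 11 of 17 tested genes had a positive interaction and 1 had a negative one (11 and 1 adjusted over the list alone, 11 and 3 with library totals alone, with camera adjusted p = 7.60e-05, and adjusted p = 0.138 with an estimated correlation).

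In chaperones and proteases 14 of 23 tested genes had a positive interaction and 2 had a negative one (15 and 2 adjusted over the list alone, 10 and 4 with library totals alone, with camera adjusted p = 4.70e-04, and adjusted p = 0.137 with an estimated correlation). 1 example is groEL at 3.06 ± 0.23. Among iron-sulfur cluster and sulfur carrier genes 13 of 20 tested genes had a positive interaction and 1 had a negative one (13 and 1 adjusted over the list alone, 9 and 2 with library totals alone, with camera adjusted p = 0.00169, and adjusted p = 0.137 with an estimated correlation). In siroheme and cobalamin synthesis 10 of 14 tested genes had a positive interaction and 3 had a negative one (10 and 3 adjusted over the list alone, with camera adjusted p = 0.00184, and adjusted p = 0.461 with an estimated correlation). In ATP synthase 2 of 15 tested genes had a positive interaction and 7 had a negative one (2 and 7 adjusted over the list alone, 0 and 9 with library totals alone, with camera adjusted p = 0.00184, and adjusted p = 0.484 with an estimated correlation). In branched-chain amino acid synthesis 10 of 12 tested genes had a positive interaction and 1 had a negative one (10 and 1 adjusted over the list alone, with camera adjusted p = 0.0173, and adjusted p = 0.555 with an estimated correlation). In purine and pyrimidine synthesis 4 of 22 tested genes had a positive interaction and 12 had a negative one (4 and 12 adjusted over the list alone, 1 and 14 with RLE factors, 1 and 16 with library totals alone, with camera adjusted p = 0.0490, and adjusted p = 0.667 with an estimated correlation). In hydrogenases and ferredoxin redox enzymes 23 of 44 tested genes had a positive interaction and 11 had a negative one (23 and 11 adjusted over the list alone, 18 and 17 with library totals alone), and their median of 0.48 was -0.06 with library totals alone (camera adjusted p = 0.00375, and adjusted p = 0.484 with an estimated correlation). The sulfate list, which holds the deleted gene, was not called, where 7 of 8 tested genes had a positive interaction and 1 had a negative one (7 and 1 adjusted over the list alone, with camera adjusted p = 0.0597). The call for purine and pyrimidine synthesis ended without control cysteine replicates 2 or 3, control sulfate replicate 2, mutant cysteine replicates 2 or 3 or mutant sulfate replicates 1 or 2 (camera adjusted p = 0.0502 to 0.0691) and with the replicate number as a block (adjusted p = 0.0630). The sulfate list passed without control cysteine replicate 1, control sulfate replicate 2, mutant cysteine replicates 1 or 3 or mutant sulfate replicate 2 (camera adjusted p = 0.00852 to 0.0428), with fry (adjusted p = 0.00541), with library totals alone (adjusted p = 0.0196) and with the replicate number as a block (adjusted p = 0.0491). Glycolysis and cellobiose use passed without mutant sulfate replicate 1 (camera adjusted p = 0.0446), with fry (adjusted p = 6.32e-04) and with library totals alone (adjusted p = 0.0497). The cellulosome list passed without control sulfate replicate 1 (camera adjusted p = 0.0483) and with fry (adjusted p = 5.91e-04). The sporulation list passed without control sulfate replicate 1, mutant cysteine replicate 1 or mutant sulfate replicates 1 or 2 (camera adjusted p = 0.0345 to 0.0440), with fry (adjusted p = 1.13e-04) and with library totals alone (adjusted p = 0.0223). The arginine, histidine and tryptophan list passed without mutant cysteine replicate 1 (camera adjusted p = 0.0397) and with fry (adjusted p = 0.0234). The CRISPR list passed with fry (adjusted p = 0.00127) and with library totals alone (adjusted p = 0.0444). Iron and metal transport passed with fry (adjusted p = 3.12e-06). Of the 9 lists not called here, pyruvate fermentation had a median, mean and test that differed in sign. With an estimated correlation no list was called in any of the 5 comparisons, where the lowest adjusted p was 0.0946.

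The interaction was called for 1712 genes, 892 more positive and 820 more negative, and 963 of them by at least 2-fold. With library totals alone 1984 were called, 486 and 1498, as the median of all genes moved from 0.07 to -0.48.

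**Figure D4:**
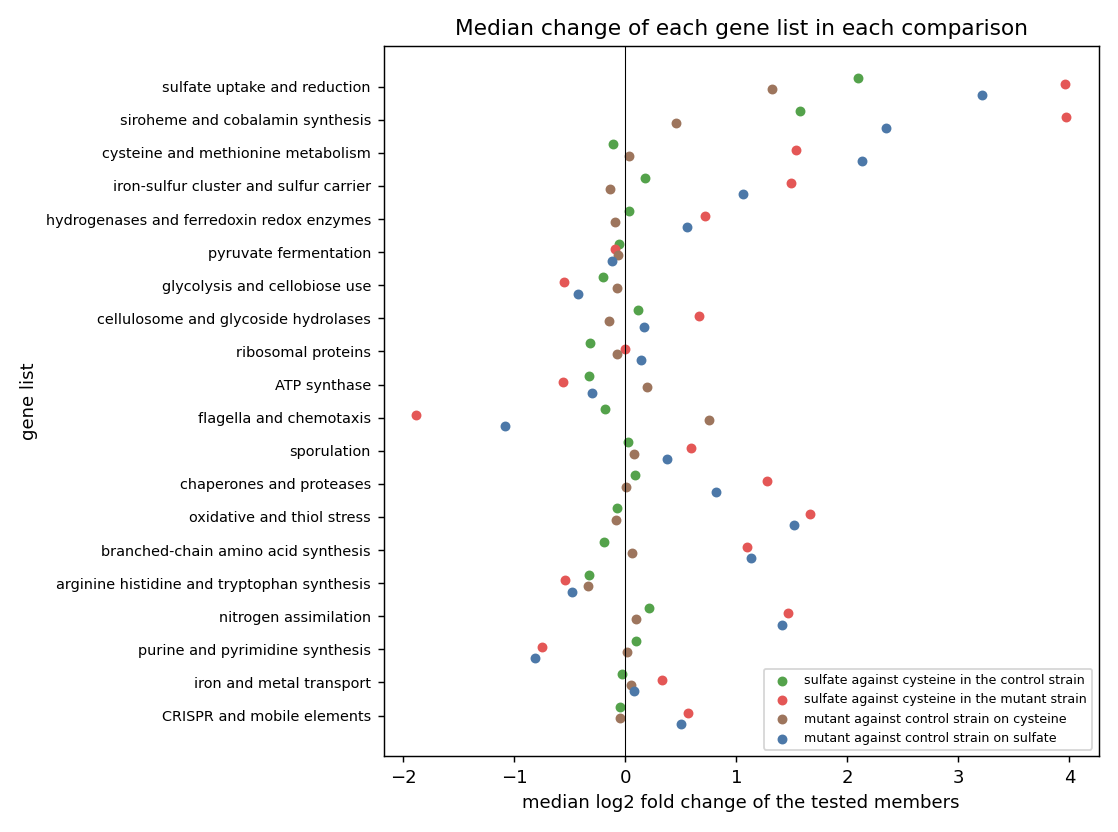
Median log2 fold change (horizontal, log2 units) of the tested members of each of 20 gene lists (vertical), 1 point per comparison. Flagella and chemotaxis lie at -1.88 for sulfate in the mutant strain and 0.76 for the strains on cysteine, and the sulfate list at 2.10 and 3.96 for sulfate in the control and mutant strains.

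Across genes, the changes with sulfate in the control and mutant strains had a Pearson correlation of 0.585 and a Spearman correlation of 0.436, without shared libraries, and genes are not independent replicates. Both strains called 296 genes higher, against 171 for independent lists, and 272 lower, against 136. A further 44 were higher in the control strain and lower in the mutant strain, against 142, and 67 the other way, against 164. The strain differences on cysteine and on sulfate had a Pearson correlation of 0.173 and a Spearman correlation of 0.0775. Of genes called in both, 156 were higher in the mutant strain on both sources, against 165 for independent lists, and 217 lower, against 147. A further 221 were higher on cysteine and lower on sulfate, against 163, and 96 the other way, against 149.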

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

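The tests of near-identical copies and of library depth were chosen before their results were seen. The counts of splits and the tests of scaling, single libraries, carried-over reads and an amplified response were chosen after.

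The interaction test gave 1712 genes whose change with sulfate differed between the strains. Of 100 splits of the libraries 1 gave as many, the real one, while the highest of the others gave 1245. The other splits shuffled libraries over all 4 groups, which also mixed the differences between strains and between sulfur sources within groups. They therefore do not test the interaction alone, and no conclusion is drawn from them. The largest differences were 4.75 for Clo1313_0392, 4.55 for Clo1313_0391, 4.45 for Clo1313_0393, 4.34 for Clo1313_0390 and 3.99 for Clo1313_0394. The most negative were -3.95 for Clo1313_1411, -3.76 for Clo1313_0707, -3.72 for Clo1313_1412, -3.71 for Clo1313_1413 and -3.48 for Clo1313_0142. Lists called for the interaction with a preset correlation had median differences of 2.40 for siroheme and cobalamin, 2.01 for cysteine and methionine, 1.04 for iron-sulfur cluster, 0.48 for hydrogenases, -0.21 for ATP synthase, -1.74 for flagella, 1.09 for chaperones, 1.85 for oxidative stress, 1.03 for branched-chain, 1.21 for nitrogen and -0.47 for purine and pyrimidine genes. With an estimated correlation none of these 11 lists was called (lowest adjusted p = 0.0946), and with library totals alone the hydrogenase median was -0.06.

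For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05, and 1 split, the real one, gave as many genes in each. The real counts were 825 and 2196 for sulfate in the control and mutant strains, and 907 and 2037 for the strains on cysteine and on sulfate, and by edgeR the highest of the other splits gave 0 in each. At an unadjusted p under 0.05 the highest of the others gave 243, 153, 289 and 149 genes, in the same order, and no other tool was run on the splits. Each of the other splits mixed libraries of both real groups, so the real difference widened the spread within its groups. Their counts are therefore no measure of false calls, and no conclusion is drawn from them.

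In the authors' deposited comparisons, 2 genes absent from the count table changed. The signal recognition particle RNA ffs was higher by 0.88 in the mutant strain on sulfate than in the control strain on sulfate, and by 0.61 than in the control strain on cysteine. CLO1313_RS15475 was higher by 1.07 and 0.91 in the same comparisons, and by 0.85 with sulfate in the mutant strain.

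Sulfate changed 1110 genes at least 2-fold in the mutant strain and 99 in the control strain. The tables argue against scaling, since the ratio of these counts was at least 9.69 under TMM, RLE and library totals, against a single library, with a lowest ratio of 9.72 without each of the 12 in turn, and against depth, with 11.2 after thinning all libraries to the lowest total. An amplified form of the control strain's response stays open, except for 18 genes that fell in the control strain and rose in the mutant strain. Of all 99 genes, 73.7% ± 4.42 (binomial SE) were called in the same direction in the mutant strain. That share is under the bound set for excluding amplification but within 1 SE of it, and neighbouring genes are not independent draws. Split by direction after that value was seen, the shares were 92.9% of 56 genes that rose and 48.8% ± 7.62 of 43 that fell. Of those 43, 18 rose in the mutant strain, among them every gene from Clo1313_2330 to Clo1313_2339. That run of neighbours moved together, so its genes are not separate evidence, and shared reads stay open for most of it. Amplification alone would not turn a fall into a rise, so these values argue against it for those 18 genes. They do not for the genes that fell in both strains. Of the 1110 genes, 349 were called in the same direction in the control strain, where smaller changes are less often called. A separate response to the loss of sulfite reduction, which the design names, may also contribute and was not tested.

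On cysteine the 7 intact sulfate list genes were higher in the mutant strain, and so were Clo1313_0372 to Clo1313_0383. Reads carried over from the mutant sulfate libraries are argued against for the sulfate genes, which would need 3.72% of those reads, 13.3 times the limit that the level of Clo1313_0372 to Clo1313_0383 sets, and so is a single library, as 7 of 7 genes were called without each cysteine library in turn. The rise was uneven, which leaving out 1 library does not test. The median of these genes was 159, 297 and 414 CPM in mutant cysteine replicates 1 to 3. In the control strain it was 110, 130 and 142 CPM. For Clo1313_0372 to Clo1313_0383 carry-over stays open. The share needed, 0.166%, is 0.837 times the 0.198% of the control sulfate level at which the deleted gene still appears in the mutant cysteine libraries. The mutant sulfate libraries lack that gene too, so its remaining reads do not measure carry-over from them, and the test cannot decide. A local effect of the deletion on its neighbours, which include the sulfate list genes cysD (Clo1313_0119) and cysNC (Clo1313_0120), was not tested.

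Genes Clo1313_2325 to Clo1313_2339 went opposite ways, where 11 of 15 were lower with sulfate in the control strain and higher in the mutant strain. The tables argue against scaling, as 11 genes did so under each of TMM, RLE and library totals. Reads shared with near-identical copies stay open, because only 2 of these 11 genes, nifD and nifH, have no other gene of the same product name or symbol, and shared names do not show shared sequence. No biological explanation was tested.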

How the results depend on the processing

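No alternative here was chosen after its result was seen. At least a 2-fold change was called for 99 genes with sulfate in the control strain, 1110 in the mutant strain, 156 between strains on cysteine, 930 on sulfate and 963 for the interaction, as a stricter threshold passes fewer genes. An adjusted p under 0.01 left 439 for sulfate in the control strain and 584 between strains on cysteine. With 1 library left out in turn, the counts were 501 to 924 for sulfate in the control strain, 2092 to 2205 in the mutant strain, 698 to 985 between strains on cysteine, 1922 to 2069 on sulfate and 1576 to 1762 for the interaction. The 2 lowest for the control strain came without control strain, cysteine replicate 2 (530) and replicate 3 (501), and the cause was not tested. Under the other tools, factors and filters each count stayed within 1.5 times of the one reported. With library totals alone, 21 of 1635 genes called both ways between strains on sulfate had the opposite sign. None of the genes named by the rule and no list was called with the opposite sign. Of 489 called results for single genes, each a gene in a comparison, 450 kept their call under all alternatives and 39 lost it under at least 1, while 2 of 7 not called gained it. Most of these genes were named for large changes or small p in these data, so their share does not stand for all genes. Over all genes, 494 of 825 calls for sulfate in the control strain stayed without control cysteine replicate 3, and 613 with library totals alone. In the mutant strain 2181 and 1826 of 2196 stayed. Of 49 called results for lists, each a list in a comparison, 9 lost their call under at least 1 alternative other than the estimated correlation, which ended all 49. Of 51 not called, 22 passed under at least 1, and 18 passed with fry, which does not compare a list with other genes. The alternatives run for lists were the estimated correlation, fry, library totals alone, the replicate block, no filter and each library left out. The list tests were not rerun under the others. The replicate numbers showed no clear pairing of the samples. Of 18 same-numbered pairs of libraries 4 had correlated deviations above 0.1, over a range of -0.217 to 0.300, and 5 of 12 libraries correlated best with their own number. These values cannot exclude a day or batch shared by some libraries. With the number as a block, 817, 2185, 882, 2018 and 1694 genes were called, in the order above. That block ended 4 list calls, for glycolysis with sulfate in the control strain (adjusted p = 0.0599), branched-chain synthesis in the mutant strain (0.0599), sporulation between strains on sulfate (0.0623) and purine and pyrimidine synthesis for the interaction (0.0630). With it the sulfate list passed for the interaction (0.0491). It also ended the calls of Clo1313_2325 (0.0570) and Clo1313_2927 (0.0529) between strains on cysteine. Genes near the floor, such as hpt with 8 to 34 counts, are measured too coarsely for small changes.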

Other observations

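The runs of adjacent genes described here were picked after their values were seen, and no further test was made on them. Each is a run of at least 5 genes that are neighbours in the count table, all called and all changed at least 2-fold. In the mutant strain on sulfate, against cysteine, 8 genes from Clo1313_0061 to Clo1313_0068, most of them encoding the Rnf complex that couples ferredoxin to NADH, rose by a median log2 fold change of 1.87. A run of 8 genes from Clo1313_2030 to Clo1313_2038 with glutamine and glutamate synthases rose by 2.49, and 10 genes from Clo1313_2490 to Clo1313_2499 with urease and urea transporter genes by 1.46. A run of 11 genes from Clo1313_2532 to Clo1313_2542, with cysteine synthase, metY and metA, rose by 2.83. The fatty acid synthesis run of 9 genes from Clo1313_1279 to Clo1313_1287 fell, with a median of -2.08, as did 9 genes from Clo1313_1262 to Clo1313_1270 of pyrimidine synthesis, with -1.52, 9 genes from Clo1313_2934 to Clo1313_2942 of the V-type ATPase, with -2.92, and 26 genes from Clo1313_1725 to Clo1313_1750 of flagellar genes, with -2.15.

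Between strains, 5 genes from Clo1313_0567 to Clo1313_0572, annotated with hydrogenase maturation and ech hydrogenase functions, were higher in the mutant strain on sulfate, with a median of 1.32, and 10 genes from Clo1313_0072 to CLO1313_RS00420, with transketolase and sugar transporter genes, were lower, with -2.02. On cysteine, 5 genes from Clo1313_2097 to Clo1313_2101, annotated with polyketide and acyl carrier functions, were lower in the mutant strain, with -1.11. The radical SAM and glycosyltransferase run from Clo1313_0136 went both ways: its median was 1.41 for the mutant strain against the control strain on cysteine and -1.46 on sulfate.

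In the authors' deposited comparisons, 1044 genes had an adjusted p under 0.05 for sulfate in the control strain, 2093 in the mutant strain, 911 between strains on cysteine and 2006 on sulfate. Of the genes called here, 815, 2016, 835 and 1962 were among them, all with the same sign.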
